A study of Mus musculus with 9 samples.

How the data were processed

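Single-cell RNA was measured in 9 libraries of nucleated living cells from the abdominal aorta of ApoE-deficient mice, a strain prone to atherosclerosis and to aortic disease under angiotensin II (Ang II). Per the labels' protocols, the aortas of each group were pooled and digested with Liberase and elastase, and droplet libraries were made from the pooled cells. Each library is therefore a pool of mice, so no p-value here measures the spread between animals. The number of mice per pool is not given in the sources used here.

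The values used were counts of unique molecular identifiers (UMIs) per gene and barcode, as the authors deposited them, without normalization. They came from Cell Ranger 3.1.0 with the mouse genome build mm10, per the submitters' processing notes, which also name Seurat 3.6.3. The matrices held whole numbers for 31053 genes, and the annotation release is not given in the sources used here. The deposited barcodes had already been called as cells and numbered 92330 in all. Total UMIs per library ran from 56886413 to 185455219. Genes are named by the symbols in the deposited tables, and a symbol shared by several identifiers was kept with its identifier.

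Barcodes with at least 500 detected genes and at most 10% mitochondrial UMIs were kept. Scrublet, as built into scanpy 1.11.5, scored doublets within each library, and its automatic calls were left out. That automatic threshold marked 0.0655% of cells in AAA and 0.0321% in IMH-II, against 3.18% in IMH-III, so an alternative that left out the highest scores at 0.8% per 1000 cells was added after the data were seen. Counts were scaled to 10000 per cell and put on a natural log scale, 2000 variable genes were chosen within libraries, and 40 principal components with 15 neighbours were clustered with Leiden (leidenalg 0.10.2) at resolution 1. No batch integration was applied. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

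The 49 clusters were named with marker lists for 22 cell classes that were fixed before the data were examined. A marker counted for a cluster when it was in at least 20% of its cells at 2 times its level in the rest or more. A class needed at least 3 such markers, and a cluster in which another class, not related by lineage, had at least 4 markers with a mean log2 fold at or above 0.5 of the first was left unnamed as mixed. A cluster with more markers of another class among its top genes, or a low mean log2 fold of its own, was also left unnamed. These naming thresholds were refined after the clusters had been seen, as was the share of cells with a Ptprc UMI (Ptprc encodes CD45) above which a cluster counted as immune. That share was raised from 30% to 40% because 1 adipocyte-like cluster reached 34.5%. Unnamed cells made up 0.840% of NA, 4.03% of AAD, 7.92% of AAA, 4.08% of IMH-I, 14.8% of IMH-II and 55.7% of IMH-III, and 15.5%, 17.3% and 14.4% of the sorted AAA, IMH-II and IMH-III libraries. They entered the shares as part of the total and no gene test.

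For each class, counts were summed per library, and libraries with fewer than 50 cells of the class were left out. Smooth muscle cells, fibroblasts and endothelial cells of AAA (5, 21 and 20 cells) and macrophages of NA (18 cells) were left out by this rule. Genes were filtered with filterByExpr at a minimum count of 10, scaled with TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment within each class and comparison. Ang II against normal was the mean over the Ang II libraries minus the 1 normal library, dissection against none was the mean of libraries with dissection minus that without, and aneurysm against none was a term added to those groups. A library alone in its arm was assumed to vary as the others do, which holds for the normal library, for AAD in the dissection test of smooth muscle cells, fibroblasts and endothelial cells, and for IMH-I in their aneurysm test. Residual degrees of freedom were 1 to 3, and the spread between libraries was estimated with information shared across genes. In smooth muscle cells, fibroblasts and endothelial cells, where AAA was left out, the aneurysm estimate compares IMH-II and IMH-III with IMH-I alone, and AAD fixes only the group without dissection. Log2 fold changes are given with standard errors (±), and levels are UMIs of the class sums scaled to a common total (CPM).

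The 20 gene lists fixed before the data were examined covered contractile genes, elastic fibre, collagen and fibrotic matrix, matrix proteases, protease inhibitors, modulated smooth muscle, TGF-beta targets, angiotensin receptor signalling, endothelial activation, angiogenic endothelium, resident-type, lipid-associated and inflammatory macrophages, interferon response, MHC class II, heme and iron handling, glycolysis and hypoxia, cell cycle, dissociation and immediate early genes, and erythroid genes. Some genes stand in more than 1 list. Lists were tested with camera in limma 3.58.1 on voom values, two-sided, at a preset correlation of 0.01, and again with an estimated correlation, under which no list call in any class or comparison held. At the preset correlation the p-values set list members against the other genes under that assumed value. They do not measure the spread between libraries alone. Members past the edgeR test were counted over all genes tested and also adjusted over the list alone.

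Genes named in the text follow a rule fixed before the data were examined. Up to 10 genes per side with the largest fold change and an adjusted p under 0.05 were taken whose groups did not overlap, with at least 50 CPM in 1 library and a class mean of at least 1 part in 4 of the highest class mean. Mitochondrial, ribosomal, hemoglobin, Gm- and Rik-named genes and markers of another class were left out of that rule. Where fewer than 5 passed on a side, the next genes were given as values only. Members of the lists are named for their list, and any other gene is marked as chosen after its values were seen.

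Shares of cells have exact (Clopper-Pearson) 95% intervals, which cover counting error only. Shares with and without dissection were compared with an exact permutation test, two-sided, whose 10 splits allow no p under 0.2. The sorted libraries, 1 per lesion, have no test, and their macrophages were compared as log2 ratios of CPM with a pseudocount of 1. Correlations between those ratios are across genes, which are not independent replicates.

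The main test was tested on simulated counts with the libraries' sizes and spread and 200 changed genes. In smooth muscle cells under Ang II it recovered 13.6% of genes changed 2-fold, 84.4% of those changed 4-fold and 98.4% of those changed 8-fold, and 22 of 148 calls were unchanged genes. In fibroblasts for aneurysm it recovered 81.5% at 4-fold, and 36 of 159 calls were unchanged genes. Unchanged genes were also 24 of 106 calls for dissection and 14 of 84 for Ang II in endothelial cells, 21 of 105 for Ang II in fibroblasts and 21 of 131 for dissection in T cells. For dissection they were 12 of 79 calls in fibroblasts and 18 of 136 in smooth muscle cells. All of these exceed the 5% that the adjusted p states. In macrophages for dissection 53.1% were recovered at 4-fold.

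DESeq2 1.42.0, upper quartile scaling, no filter on low counts, a looser cell filter (200 genes, 20% mitochondrial UMIs), doublet calls kept, resolutions 0.5 and 2, equal cell numbers, other sets of libraries and the removal of each Ang II library in turn were run as alternatives. Alternatives added after the data were seen were the doublet rate above, libraries with at least 5 cells, cluster 10 added to the macrophages and the 30% Ptprc level.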

Results

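The data are droplet single-cell RNA counts from the abdominal aorta of ApoE-deficient mice, either untreated or given Ang II, a pressor peptide used to induce dissecting abdominal aortic aneurysm, for 4 weeks. The study asks how the cells of the aortic wall differ between lesions 28 days after the start of Ang II. The library names used here are those of the labels. NA is the normal aorta. Without dissection there were 2 Ang II libraries, AAD from a dilated aorta and AAA from an aorta with a single aneurysm. With dissection, meaning a tear or intramural hematoma, there were 3 libraries, IMH-I without aneurysm, IMH-II with a single aneurysm and IMH-III with several. For AAA, IMH-II and IMH-III there was also 1 library each of sorted immune cells. Total UMIs were 97368798 in NA, 84495483 in AAD, 56886413 in AAA, 89390643 in IMH-I, 66866388 in IMH-II and 185455219 in IMH-III. Median UMIs per barcode were 11328.5, 5963, 5249, 4476, 5889.5 and 9335 in the same order, and 7496, 7315, 6100, 8727, 6226 and 12468 cells were kept. The sorted libraries held 87622181, 76771109 and 74716999 UMIs, with 12994, 10652 and 10376 cells kept for AAA, IMH-II and IMH-III.

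Smooth muscle cells, the contractile cells of the aortic media, made up 66.8% of kept cells in the normal library (95% exact interval 65.7% to 67.9%) and 0.0820% to 7.51% in the 5 Ang II libraries (mean 3.26% ± 2.98, SD). Among non-immune cells alone they were 72.2% in NA, and 27.9%, 2.69%, 36.7%, 7.24% and 2.30% in AAD, AAA, IMH-I, IMH-II and IMH-III. Immune clusters made up 7.44% of the normal library, and 82.0% in AAD, 97.0% in AAA, 79.6% in IMH-I, 68.0% in IMH-II and 39.5% in IMH-III. T cells were 1.97% of the normal library, 28.0% of AAD and 55.8% of AAA, and B cells 3.04%, 35.0% and 15.7%, values for which no test was planned. Macrophages were 0.240% of normal cells (0.142% to 0.379%), 3.88% in AAD, 1.82% in AAA, 1.81% in IMH-I, 8.30% in IMH-II and 18.8% in IMH-III (18.1% to 19.5%). Among immune cells alone they were 3.23% in NA and 47.6% in IMH-III. These shares leave out unnamed cluster 10, which held all 8 macrophage markers and made up 2.10% of AAA and 6.44% of IMH-II. Fibroblasts ranged from 0.344% in AAA to 19.5% in IMH-II, and among non-immune cells they were 16.9% in NA, 40.3% in AAD, 11.3% in AAA, 49.7% in IMH-I, 61.0% in IMH-II and 1.31% in IMH-III. Neutrophils ranged from 0.400% in NA to 14.1% in IMH-I. Plasma cells were 3.46% of AAD, and 0 of 7496 cells were found in the normal library, with an upper limit of 0.0492%. Schwann cells, the glia of peripheral nerves, were 4.03% of the normal library and at most 0.505% in any Ang II library. Unnamed clusters took 55.7% of IMH-III, against 0.840% of NA and 4.03% to 14.8% of the other Ang II libraries. Among non-immune cells they were 89.6% in IMH-III and 75.3% in AAA.

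With dissection (n = 3) against without (n = 2), T cells averaged 14.2% ± 7.42 (SD) and 41.9% ± 19.7, with every library with dissection lower (exact permutation test, two-sided, p = 0.2, the smallest that 10 splits allow). The difference of -27.7 points became -41.7 without AAD and -13.8 without AAA. Plasma cells, the antibody-secreting B-lineage cells, averaged 0.445% ± 0.554 with dissection and 2.61% ± 1.21 without (exact p = 0.2), a difference of -2.16 points that was -1.31 without AAD. Schwann cells averaged 0.362% ± 0.191 and 0.0410% ± 0.0580 (exact p = 0.2). Macrophages averaged 9.63% ± 8.56 and 2.85% ± 1.46 (exact p = 0.6), a difference of 6.78 points that was 2.21 without IMH-III. B cells averaged 18.4% ± 14.0 and 25.4% ± 13.7 (exact p = 0.6), and that difference turned to 2.73 points without AAD. Smooth muscle cells averaged 3.74% ± 3.29 and 2.55% ± 3.49 (exact p = 0.8), and that difference turned to -1.28 without AAA. For the 19 classes tested, p adjusted over classes lay between 0.95 and 1.

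**Figure D1:**
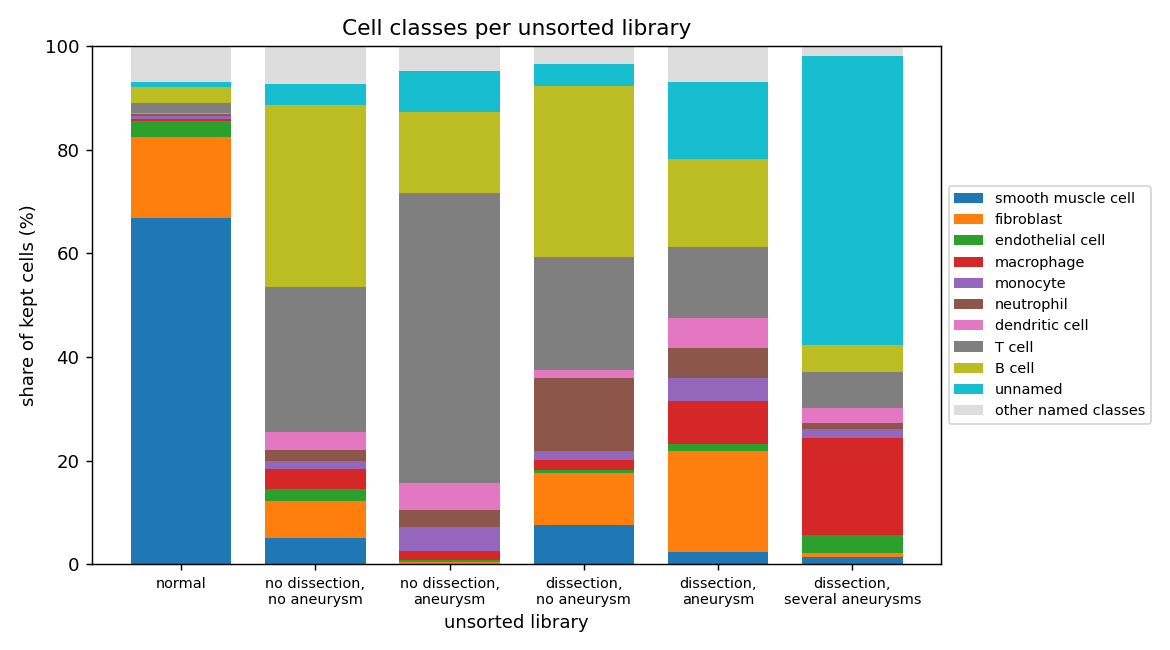
Stacked bars give the share of kept cells in each class, in percent of all kept cells, for each of the 6 unsorted libraries. Smooth muscle cells fill 66.8% of the normal bar, immune classes most of AAD, AAA, IMH-I and IMH-II, and unnamed clusters 55.7% of IMH-III.

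Ang II against normal asks which genes of the resident wall cells differ after 4 weeks of the peptide. In every class the normal arm was NA alone, so these calls set NA apart from the Ang II libraries and cannot tell Ang II from what else was particular to that pool. In smooth muscle cells (4 Ang II libraries, 144 to 655 cells each, against 1 normal library with 5007) 125 genes rose and 15 fell (edgeR). Scx, a transcription factor of tendon and other tension-bearing tissue, rose by 1.90 ± 0.32 on the log2 scale, from 33.1 CPM in NA to 106 to 160 CPM (adjusted p = 0.0313). S100a4, a calcium-binding protein of motile cells, rose by 2.49 ± 0.39 from 207 CPM to 795 to 1372 CPM (adjusted p = 0.0237), a gene at 2392 CPM in monocytes. Among genes that fell were Adam33, a membrane metalloprotease of smooth muscle, with a log2 change of -1.46 ± 0.20 (60.6 CPM to 19.2 to 26.7 CPM, adjusted p = 0.0159). Ntrk3, a neurotrophin receptor, stood at -1.30 ± 0.21 (adjusted p = 0.0245). Bex4, Cdc42ep3, Gpsm2 and Stum fell by 1.28, 1.22, 1.17 and 1.17.

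The contractile genes of smooth muscle did not pass, with a list median of -0.18 (adjusted p = 0.168) and 0 of 16 members past the test. The class was named by Myh11, Acta2, Tagln, Cnn1, Lmod1 and Des, all on this list. A cluster that lost them would be left out of the class, so the test cannot show such a loss. In IMH-III, unnamed cluster 4 held the list at 22.8% of its median in the named smooth muscle cells. Myh11, the smooth muscle myosin heavy chain, stood at -0.39 ± 0.25 (adjusted p = 0.703) and Des, desmin, at -0.92 ± 0.32 (adjusted p = 0.290). Collagen and fibrotic matrix rose with a median of 1.08 (adjusted p = 6.47e-09, and adjusted p = 0.279 with an estimated correlation), with 1 of 20 members past the test, Comp, a cartilage and tendon matrix protein, and 11 adjusted over the list alone. Matrix proteases rose with a median of 1.15 (adjusted p = 1.13e-07, and 0.272 with an estimated correlation), 8 of 18 members adjusted over the list alone. Mmp2, a gelatinase, stood at 1.43 ± 0.27 and Ctss, a lysosomal elastase, at 4.11 ± 0.69. Modulated smooth muscle genes rose with a median of 1.41 (adjusted p = 2.87e-07, and 0.272 with an estimated correlation), 3 of 17 past the test and 10 adjusted over the list alone. Among the 3 were Lgals3 at 2.02 ± 0.27 and Ly6a at 2.49 ± 0.34. Lgals3 also stands in the lipid-associated macrophage list. List members were named without the criterion on levels in other classes, so RNA from other cells is not excluded for them. Protease inhibitors had a median of 0.43 (adjusted p = 0.00439, and 0.279 with an estimated correlation), with Timp1, an inhibitor of matrix metalloproteases, at 3.57 ± 0.61, 1 of 9 past the test and 3 adjusted over the list alone. TGF-beta targets had a median of 0.94 (adjusted p = 2.25e-05, and 0.279 with an estimated correlation), 0 of 14 past the test and 5 adjusted over the list alone. Elastic fibre genes (median 0.43, adjusted p = 0.279), angiotensin receptor signalling (0.17, 0.216), resident-type macrophage genes (0.13, 0.687), glycolysis and hypoxia (0.22, 0.152) and heme and iron handling (adjusted p = 0.687, median -0.08 while the mean was 0.24 and the test pointed up) did not pass.

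Lists made of immune genes rose in the same smooth muscle cells. MHC class II, which presents antigen on immune cells, had a median of 4.45 (adjusted p = 4.84e-12, and 0.206 with an estimated correlation), 4 of 7 past the test and 6 adjusted over the list alone. Its member H2-Ab1 went from 2.03 to 40.6 to 49.0 CPM, beside 9439 CPM in dendritic cells. Inflammatory macrophage genes had a median of 3.56 (adjusted p = 2.84e-12, and 0.206 with an estimated correlation), 4 of 15 past the test, with the neutrophil attractant Cxcl2 at 3.80 ± 0.38, and 14 adjusted over the list alone. Lipid-associated macrophage genes (median 1.54, 2 of 16 past the test, 6 adjusted over the list alone), endothelial activation (3.34, 4 of 11, 10 adjusted over the list alone), angiogenic endothelium (1.05, 1 of 10, 3 adjusted over the list alone), interferon response (0 of 13) and cell cycle (1.34, 0 of 12) rose as well. Dissociation and immediate early genes (-0.61, 0 of 14, 5 lower adjusted over the list alone) and erythroid genes (-1.11, 0 of 4) fell. Their adjusted p lay between 3.51e-08 and 0.00672, and between 0.272 and 0.438 with an estimated correlation. Of the 140 genes past the test 137 did not overlap between groups (44.5% of all tested genes, where chance gives 40%). Only 9 of the 140 met every criterion of the naming rule, which asks among others for 1 part in 4 of the highest class mean. The count was 10 with equal cell numbers, 33 with doublet calls kept, 372 without IMH-I, 718 without IMH-II, 511 without IMH-III and 281 with libraries of at least 5 cells, which bring in 5 cells of AAA.

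In fibroblasts, the matrix-making cells of the outer wall, 20 genes rose and 12 fell (4 Ang II libraries against 1). Col12a1, a fibril-associated collagen, rose by 4.14 ± 0.53 from 16.8 CPM to 118 to 522 CPM (adjusted p = 0.0405). P4ha3, a collagen prolyl hydroxylase, rose by 5.13 ± 0.46 from 1.43 CPM to 17.2 to 81.8 CPM (adjusted p = 0.0270). Fbn2, a microfibril protein of developing elastic tissue, rose by 5.33 ± 0.71, Acan, the cartilage proteoglycan aggrecan, by 4.39 ± 0.59, and Il4ra, a subunit of the receptors for IL-4 and IL-13, by 3.13 ± 0.41. Gsn, the actin-severing protein gelsolin, fell by 3.02 on the log2 scale (± 0.35, 20919 CPM to 1606 to 5032 CPM, adjusted p = 0.0405) and C7, a complement component, by 3.35 (± 0.26, 277 CPM to 15.5 to 91.8 CPM, adjusted p = 0.0171). Sult1e1, an estrogen sulfotransferase, fell by 4.26 (± 0.55), a call that DESeq2 did not make.

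Collagen and fibrotic matrix rose in fibroblasts with a median of 1.24 (adjusted p = 3.74e-13, and 0.360 with an estimated correlation), 2 of 20 past the test and 12 higher and 1 lower adjusted over the list alone. Its member Thbs1, a matrix glycoprotein that activates latent TGF-beta, went from 57.6 CPM to 259 to 1142 CPM (adjusted p = 0.0405). Contractile genes fell with a median of -1.80 (adjusted p = 1.83e-09, and 0.454 with an estimated correlation), 0 of 16 past the test and 10 adjusted over the list alone, among them Myh11 at -3.06 ± 0.50 (adjusted p = 0.0685). In T cells, which do not make muscle myosin, contractile RNA was also 1325 CPM in NA against 44.7 to 336 CPM in the Ang II libraries. Elastic fibre (median 0.72), matrix proteases (0.65, with Ctss at 4.58 ± 0.53), modulated smooth muscle (0.73), TGF-beta targets (0.77), endothelial activation (2.30, with Lrg1 at 4.38 ± 0.55), lipid-associated macrophage (0.93), inflammatory macrophage (3.61), interferon response (0.65), MHC class II (2.78) and cell cycle (2.89) rose (adjusted p = 8.70e-08 to 0.0492, and 0.454 to 0.608 with an estimated correlation). In the Ang II libraries the MHC class II and inflammatory genes of fibroblasts stood at a median of 2.88% to 15.5% of their level over all cells, and B cell, T cell and neutrophil markers at 5.51% to 7.71%. Taken apart, the inflammatory genes stood at 23.5%, 8.80%, 9.31% and 3.19% in AAD, IMH-I, IMH-II and IMH-III, and MHC class II at 7.39%, 6.99%, 5.11% and 2.88%. In normal fibroblasts the inflammatory genes stood at 169% and MHC class II at 12.6%, beside 26.6% for 7 marker genes. Protease inhibitors did not pass (adjusted p = 0.491, median -0.19, mean 0.14, test down). All normal fibroblasts lay in cluster 13, led by Pi16 and Clec3b, which held 91.7% of those of AAD, 76.6% in IMH-I, 27.0% in IMH-II and 37.4% in IMH-III. The remainder lay in cluster 18, led by Cthrc1, Comp and Cpxm2. The count of 32 became 867 without IMH-I, 238 without IMH-II, 120 without IMH-III, 61 without AAD, 0 with equal cell numbers, and 1, lower, with libraries of at least 5 cells, which bring in AAA. All 32 were non-overlapping (51.7% of tested genes, 40% by chance).

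In endothelial cells, which line the vessel, 28 genes rose and 51 fell. None of these calls was left without IMH-II or with libraries of at least 5 cells, which bring in AAA, while the count was 221 without AAD, 491 without IMH-I and 215 without IMH-III. Mmp14, a membrane-bound matrix protease of sprouting vessels, rose by 4.01 ± 0.32 from 10.3 CPM to 61.3 to 238 CPM (adjusted p = 0.0265). Angptl4, an inhibitor of lipoprotein lipase, rose by 4.90 ± 0.52 from 4.80 CPM to 115 to 177 CPM (adjusted p = 0.0342). Mest, an imprinted gene, rose by 5.90 ± 0.73, Marcksl1 by 4.34 ± 0.35 and Ctla2a by 3.63 ± 0.35. Adra2a, the alpha-2A adrenergic receptor, fell by 7.56 on the log2 scale (± 0.34, 160 CPM in NA, 11.9 in AAD and at most 0.424 in the other 3, adjusted p = 0.00862). Cytl1, a secreted cytokine-like protein, fell by 4.44 (± 0.34, 8062 CPM to 136 to 1878 CPM), and Gkn3, a marker of arterial endothelium, fell by 3.58 (± 0.29, 733 CPM to 28.2 to 231 CPM). Angiogenic endothelium rose with a median of 2.66 (adjusted p = 0.000633, and 0.568 with an estimated correlation), 2 of 13 past the test, the basement membrane collagens Col4a1 at 2.38 ± 0.30 and Col4a2 at 2.66 ± 0.31, and 4 adjusted over the list alone. Erythroid genes fell with a median of -3.96 (adjusted p = 1.45e-06, and 0.568 with an estimated correlation), 2 of 5 past the test, although Hbb-bt was 569 CPM in AAD, 279 in NA and at most 6.35 in the 3 libraries with dissection. Collagen (median 1.36), matrix proteases (1.80), lipid-associated (2.24) and inflammatory macrophage genes (6.31, with Ccl2 at 6.98 ± 0.70), MHC class II (3.80), glycolysis (1.11) and cell cycle (2.10, 0 of 14 past the test and 10 adjusted over the list alone) rose, and contractile genes (-1.21) and interferon response (-0.78) fell (adjusted p = 0.000558 to 0.0141, and 0.568 to 0.611 with an estimated correlation). By library the contractile median over NA was 0.26 in IMH-I, against -2.00 in AAD, -2.10 in IMH-II and -1.80 in IMH-III. In the Ang II libraries the MHC class II and inflammatory genes stood at a median of 2.75% to 17.6% of their level over all cells. B cell, T cell and neutrophil markers stood at 1.23% to 12.5%. The ratio to those markers was 1.41 in AAD, 4.47 in IMH-I, 0.956 in IMH-II and 0.711 in IMH-III, beside 8.13 in NA. Endothelial cluster 46 held 15.2% of these cells in AAD, 3.39% in NA and 0% with dissection. At resolution 2 a cluster led by Igfbp3 and Apln, singled out after its values were seen, held 0 cells of NA, 12 of AAD, 8 of IMH-I, 26 of IMH-II and 355 of IMH-III. Of the 79 calls 76 were non-overlapping (62.1% of tested genes, 40% by chance).

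**Figure D2:**
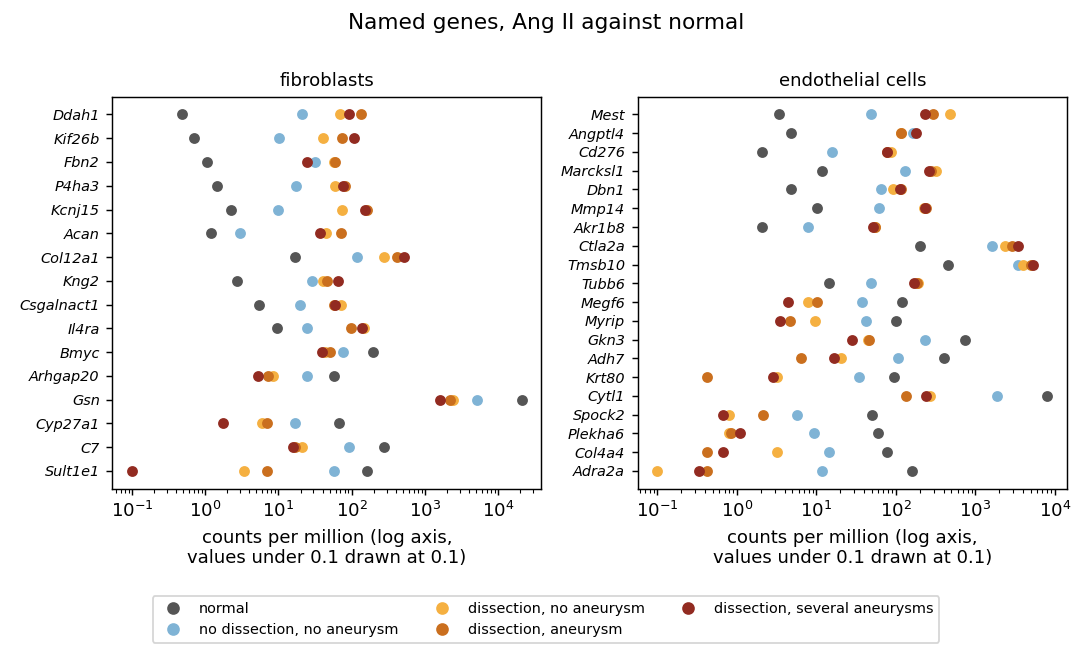
Points give CPM (log axis, values under 0.1 drawn at 0.1) of the named genes past the test in fibroblasts and endothelial cells, 1 point per library. For Gsn in fibroblasts the normal library stands at 20919 and the 4 Ang II libraries between 1606 and 5032.

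In T and B cells (6 libraries) no gene passed the edgeR test for Ang II. For T cells 603 genes had an unadjusted p under 0.05 and DESeq2 called 4, and for B cells 438 and 0. In the simulation, with 12017 genes in T cells and 10060 in B cells, 4.69% and 4.87% of unchanged genes reached that p. Counts near these can therefore arise with no gene changed. Tnfrsf9, a costimulatory receptor of activated T cells, was 2.41 CPM in normal T cells and 34.1 to 66.4 CPM in the 5 Ang II libraries (4.53 ± 0.74, adjusted p = 0.789). Tnfrsf4, another such receptor, was 32.6 CPM and 97.1 to 272 CPM (2.47 ± 0.57, adjusted p = 0.904). Cell cycle genes rose in T cells with a median of 0.51 and 0 of 14 past the test (adjusted p = 0.00108, and 0.813 with an estimated correlation). Contractile genes fell with a median of -2.56 in T cells and -2.70 in B cells (adjusted p = 2.42e-15 and 2.93e-27, and 0.688 and 0.603 with an estimated correlation), beside their 73319 CPM over all normal cells and 979 to 17131 CPM over all cells of the Ang II libraries. Collagen (median 1.39), inflammatory macrophage (6.27), interferon response (0.53) and MHC class II genes (4.02) rose in T cells and angiotensin receptor signalling (-0.36) fell (adjusted p = 0.000698 to 0.0352, and 0.577 to 0.878 with an estimated correlation). In B cells collagen (1.70) and inflammatory macrophage genes (6.13) rose (adjusted p = 0.00373 and 0.00109, and 0.821 and 0.603 with an estimated correlation). Dissociation genes in T cells tested lower (adjusted p = 0.0234, and 0.812 with an estimated correlation) with a median of -0.27 and a mean of 0.24. Without AAD the counts were 6 genes in T cells and 3 in B cells.

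Dissection against none asks what sets a torn or bled wall apart from an Ang II wall without a tear. In smooth muscle cells, fibroblasts and endothelial cells the arm without dissection was AAD alone, so their calls set AAD apart from 3 libraries and cannot tell dissection from what else was particular to AAD. The 1 gene higher in smooth muscle cells was Cxcl2, by 3.20 ± 0.38, from 13.7 CPM to 90.5 to 145 CPM (adjusted p = 0.0276), beside 14164 CPM in monocytes. The 6 genes that fell, chosen for mention after their values were seen, were the neutrophil granule genes Camp, Ngp and Ltf, the immunoglobulin gene Iglc1, and the lymphoid chemokine genes Cxcl13 and a copy of Ccl21a. None of the 7 met every criterion of the naming rule, which asks among others for 1 part in 4 of the highest class mean. Inflammatory macrophage genes rose with a median of 2.81 (adjusted p = 1.03e-15, and 0.244 with an estimated correlation), 1 past the test and 9 adjusted over the list alone. Il6 stood at 3.06 ± 0.56 (adjusted p = 0.367) and Adamts4, an aggrecan-cleaving protease, at 2.06 ± 0.34 (4.30 CPM in AAD and 16.2 to 20.3 CPM with dissection, adjusted p = 0.299). Matrix proteases (0.41), modulated smooth muscle (0.36), endothelial activation (0.93) and heme handling (0.26) rose, and cell cycle (-0.58) and dissociation genes (-0.56, 0 past the test and 4 adjusted over the list alone) fell (adjusted p = 7.97e-11 to 0.0493, and 0.590 with an estimated correlation). The count of 7 (all non-overlapping, 36.1% of tested genes and 50% by chance) became 76 without IMH-I, 27 without IMH-II and 36 without IMH-III. DESeq2 called 17, and 1 passed with equal cell numbers. The Cxcl2 call ended with equal cell numbers (3.46, adjusted p = 0.326), the looser cell filter (2.30), doublet calls kept (1.33) and doublets by expected rate (2.01).

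In fibroblasts Cxcl13, the chemokine that draws B cells into follicles, fell by 3.59 on the log2 scale (± 0.28, adjusted p = 0.00875), from 929 CPM in AAD to 72.4, 79.6 and 80.3 CPM with dissection, beside 190.0 CPM in the normal library. The other 2 genes past the test, named after their values were seen, were the immunoglobulin light chain genes Iglc1 and Iglc3. Plasma cells made up 3.46% of AAD against at most 1.08% of the libraries with dissection. Collagen and fibrotic matrix rose with a median of 0.51, 18 of 20 members positive, 0 past the test and 1 adjusted over the list alone (adjusted p = 2.95e-08, and 0.569 with an estimated correlation). Acan stood at 4.12 ± 0.55 (adjusted p = 0.183), and Agt, the precursor of Ang II itself, at -2.77 ± 0.63 (adjusted p = 0.675). Modulated smooth muscle (0.65) and TGF-beta targets (0.15) rose, and angiotensin receptor signalling (-0.46), contractile genes (-0.42), endothelial activation (-1.18), interferon response (-0.16), cell cycle (-0.70) and dissociation genes (-0.41) fell (adjusted p = 0.000925 to 0.0444, and 0.700 with an estimated correlation). The count of 3 (41.4% of tested genes non-overlapping, 50% by chance) became 338 without IMH-I, 13 without IMH-II, 10 without IMH-III, 0 with equal cell numbers and 54 with aneurysm as a term. It was 0 with libraries of at least 5 cells, which bring in AAA, where Cxcl13 stood at -2.70 (adjusted p = 1.00).

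In endothelial cells the only gene past the test was the hemoglobin gene Hbb-bt, which fell by 7.11 on the log2 scale (± 0.37, adjusted p = 0.0196). That call was absent without IMH-II and with libraries of at least 5 cells, and 160 genes passed without IMH-I, 7 without IMH-III and 127 with DESeq2. Angiogenic endothelium rose with a median of 2.00, 11 of 13 members positive, 0 past the test and 3 adjusted over the list alone (adjusted p = 0.000261, and 0.499 with an estimated correlation). Mmp14 stood at 1.92 ± 0.26 (61.3 CPM in AAD and 225 to 238 CPM with dissection, adjusted p = 0.137). Apln, the tip cell peptide apelin, was at 34.0 CPM in AAD and 24.6, 40.2 and 785 CPM in IMH-I, IMH-II and IMH-III (adjusted p = 0.714). MHC class II fell with a median of -1.91, 0 of 6 past the test and 6 adjusted over the list alone (adjusted p = 1.61e-06, and 0.499 with an estimated correlation), and erythroid genes with a median of -6.58 (adjusted p = 2.68e-10, and 0.499 with an estimated correlation). Hemoglobin took 0.851% of all UMIs in AAD, and 0.843%, 0.333% and 0.185% in IMH-I, IMH-II and IMH-III. Cell cycle (1.34), glycolysis (0.71) and matrix proteases (0.55) rose, and interferon response (-0.54), resident-type macrophage genes (-1.97), protease inhibitors (-1.04) and dissociation genes (-0.69) fell (adjusted p = 8.44e-06 to 0.0337, and 0.499 to 0.760 with an estimated correlation).

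In macrophages (3 libraries against 2) no gene passed the edgeR test for dissection, 296 had an unadjusted p under 0.05 and DESeq2 called 9. Of unchanged genes in the simulation, which held 9984 genes, 4.62% reached that p, so a count of 296 can arise with no gene changed. Spp1, the secreted matrix protein osteopontin, was 820 and 1260.0 CPM in AAD and AAA and 2969, 2857 and 3467 CPM in IMH-I, IMH-II and IMH-III (1.58 ± 0.28). Vegfa, the endothelial growth factor, was 53.8 and 23.3 CPM and 163, 95.5 and 187 CPM (1.92 ± 0.46, adjusted p = 1.00). Gclm, which makes glutathione, was 37.2 and 39.6 CPM and 103, 83.0 and 90.5 CPM (1.26 ± 0.22), again with an adjusted p of 1.00. Interferon response genes fell with a median of -0.92 and 0 of 15 positive (adjusted p = 5.49e-12, and 0.248 with an estimated correlation). MHC class II fell with a median of -0.68 (adjusted p = 9.39e-08, and 0.294 with an estimated correlation), and glycolysis and hypoxia rose with a median of 0.52 (adjusted p = 5.98e-06, and 0.294 with an estimated correlation), with 0 members past the test in each. Heme and iron handling rose with a median of 0.16 (adjusted p = 0.0237, and 0.294 with an estimated correlation), where Hmox1, heme oxygenase, was 817 and 101 CPM without and 3472, 1111 and 734 CPM with dissection. Resident-type genes (-1.33), endothelial activation and dissociation genes (-0.51) fell and elastic fibre (0.68), matrix proteases (0.62), TGF-beta targets (0.20), collagen, contractile, angiogenic and cell cycle genes (0.26) rose (adjusted p = 2.47e-05 to 0.0409, and 0.294 to 0.493 with an estimated correlation). Without AAA 16 genes passed.

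T cells with dissection had lower cell cycle genes, with a median of -1.83, 0 of 14 positive, 0 past the test and 13 adjusted over the list alone (adjusted p = 6.53e-22, and 0.169 with an estimated correlation). Ube2c, a ubiquitin-conjugating enzyme of mitosis, was 88.1 and 180.0 CPM in AAD and AAA and 26.7, 34.1 and 35.8 CPM with dissection (-2.07 ± 0.32, adjusted p = 0.195). The cycling cluster held 3.13% and 7.05% of T cells against 2.26%, 1.52% and 1.26%. TGF-beta targets rose in T cells with a median of 1.02, 0 of 14 past the test and 5 adjusted over the list alone (adjusted p = 6.21e-09, and 0.169 with an estimated correlation). Collagen genes rose with a median of 2.67 in T cells and 2.56 in B cells, all 20 positive in each (adjusted p = 1.62e-27 and 2.23e-34, and 0.169 and 0.237 with an estimated correlation), beside collagen over all cells at 12430 and 4132 CPM without dissection and 32174, 39493 and 38220 CPM with it. Another 13 lists rose in T cells, with medians of 0.31 to 2.18 (adjusted p = 3.42e-13 to 0.00717, and 0.169 to 0.240 with an estimated correlation). In B cells 11 more rose, with medians of 0.63 to 2.36 (adjusted p = 1.75e-12 to 0.0163, and 0.237 to 0.397 with an estimated correlation), and interferon response fell (-1.39, adjusted p = 0.0420, and 0.627 with an estimated correlation). No single gene passed in either class. An unadjusted p under 0.05 was reached by 875 in T cells and 304 in B cells, and DESeq2 called 61 and 6. In the simulation, with 12036 genes in T cells and 10084 in B cells, 4.87% and 4.82% of unchanged genes reached that p. The 304 in B cells can therefore arise with no gene changed. Without AAD 183 genes passed in T cells and 31 in B cells.

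Aneurysm against none, with dissection in the same fit, asks which genes go with a formed aneurysm within the Ang II aortas. In macrophages (AAA, IMH-II and IMH-III against AAD and IMH-I) 17 genes rose and 79 fell. Cd163, the scavenger receptor for hemoglobin bound to haptoglobin, fell by 8.73 on the log2 scale (± 0.33, adjusted p = 0.00210), from 287 and 143 CPM in AAD and IMH-I to at most 0.372 CPM in each of the 3 aneurysm libraries, a call kept without any 1 library. Resident-type macrophage genes fell with a median of -4.45 (adjusted p = 1.04e-16, and 0.755 with an estimated correlation), 7 of 12 past the test and all 12 adjusted over the list alone. Among them Mrc1, the mannose receptor, stood at -3.42 ± 0.28 (1272 and 1039 CPM against 79.8, 111 and 148) and Ccl24, an eosinophil attractant, at 169 and 151 CPM against 0, 1.84 and 0.465. The monocyte attractant Ccl8 fell by 3.85 (± 0.48, adjusted p = 0.0356), from 4121 and 1935 CPM to 139, 171 and 293 CPM. Itgax, the integrin CD11c, rose by 3.02 ± 0.35 (17.8 and 14.8 CPM to 177, 70.5 and 126 CPM, adjusted p = 0.0326). The signalling regulator Rgs1 rose by 2.00 ± 0.16 and Lgals3, the lectin galectin-3, by 2.09 ± 0.21.

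Lipid-associated macrophage genes rose with a median of 0.93 (adjusted p = 1.70e-08, and 0.755 with an estimated correlation), 1 of 16 past the test and 10 adjusted over the list alone, with Trem2, a lipid receptor, at 1.59 ± 0.28 (adjusted p = 0.0689). Endothelial activation genes fell with a median of -1.39 (adjusted p = 0.00888, and 0.755 with an estimated correlation), 2 of 9 past the test, the adhesion molecule Vcam1 at -1.99 ± 0.22 and Ccl2 at -1.39 ± 0.18. Cluster make-up differed in the same direction, since cluster 34, led by Folr2, Cd163 and Lyve1, held 213 of 284 macrophages in AAD, 44.3% in IMH-I, and 0%, 4.64% and 0.342% in AAA, IMH-II and IMH-III. Cluster 2, led by Gpnmb and Trem2, held 20.4% and 48.1% against 84.7% to 91.9%. In the sorted libraries of AAA, IMH-II and IMH-III, cluster 34 held 8.62%, 2.61% and 8.50% of macrophages, and no lesion without aneurysm was sorted. Of the 96 calls 94 were non-overlapping (43.1% of tested genes, 20% by chance). The count was 3 without AAD, 7 without AAA, 16 without IMH-I, 56 without IMH-II, 237 without IMH-III, and 8 when cluster 10 was added.

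Fibroblasts of IMH-II and IMH-III, set against IMH-I, had 71 genes higher and 270 lower. With IMH-I the only library in that arm and 1 residual degree of freedom, the calls set IMH-I apart and cannot tell aneurysm from what else was particular to it, which holds for smooth muscle and endothelial cells too. Spp1 rose by 3.45 ± 0.46 (236 CPM in AAD, 317 in IMH-I, 2396 in IMH-II and 4519 in IMH-III, adjusted p = 0.00496) and Comp by 2.42 ± 0.34 (104 and 229 CPM against 1061 and 1389, adjusted p = 0.00674). Chad, a cartilage matrix protein, rose by 5.86 ± 1.16, Rspo3, a Wnt enhancer, by 2.44 ± 0.45, and Mdk, the growth factor midkine, by 1.91 ± 0.37, and these 3 calls were lost without AAD. Rbp4, a retinol carrier, fell by 3.97 (± 0.30, 693 and 766 CPM against 54.8 and 40.6, adjusted p = 0.000238), Ptx3, a pentraxin of innate immunity, by 4.47 (± 0.33), and Dio2, which activates thyroid hormone, by 3.62 (± 0.28). The basement membrane genes Col4a3, Col4a4 and Lamc3 fell by 3.62, 3.49 and 3.82, calls that DESeq2 did not make.

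Contractile genes fell in those fibroblasts (median -0.84, 1 of 16 past the test and 7 adjusted over the list alone), as did endothelial activation (-0.55, with Cxcl1 at -2.26 ± 0.29 and Ccl2 at -3.00 ± 0.39 among 3 past the test). Angiogenic endothelium (-0.20, 3 past the test), resident-type macrophage genes (-1.93, 1 past the test), glycolysis (-0.56, 2 past the test), cell cycle (-1.14, 2 of 14 past the test) and dissociation genes (-0.43) fell too. Interferon response rose with a median of 0.87, 0 of 15 past the test and 6 adjusted over the list alone, and lipid-associated genes with 0.53. Erythroid genes fell with a median of -3.88, 4 of 4 past the test. Adjusted p for these 10 lists lay between 1.04e-06 and 0.0335, and was 0.774 with an estimated correlation. Cluster 18 held 23.4% of fibroblasts in IMH-I, 73.0% in IMH-II and 62.6% in IMH-III. Of the 341 calls 308 were non-overlapping (46.4% of tested genes, 33.3% by chance). The count was 202 without AAD, 132 with DESeq2, 157 with equal cell numbers and 58 with libraries of at least 5 cells, which bring in AAA.

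In smooth muscle cells, again against IMH-I, 28 genes rose and 45 fell for aneurysm. Frzb, a secreted Wnt antagonist, rose by 2.91 ± 0.41 (33.0 CPM in AAD, 11.4 in IMH-I, 74.3 in IMH-II and 97.2 in IMH-III, adjusted p = 3.12e-09), and Lum, a collagen-binding proteoglycan, by 3.14 ± 0.42 (adjusted p = 1.15e-10). Spp1 rose by 2.71 ± 0.47, although its 164 CPM in IMH-I lay above the 111 CPM of IMH-II, with 2034 CPM in IMH-III. Pln, the calcium pump regulator phospholamban, rose by 1.60 ± 0.39 and Jag1, a Notch ligand, by 1.46 ± 0.38, calls that DESeq2 did not make. Errfi1, an inhibitor of the EGF receptor, fell by 2.23 (± 0.37, 451 CPM in IMH-I, 90.8 and 101 CPM with aneurysm, and 115 CPM in AAD, adjusted p = 1.37e-06). Lipid-associated macrophage genes rose with a median of 0.98, 2 of 16 past the test and 3 adjusted over the list alone, as did modulated smooth muscle (0.31, 2 past the test) and interferon response (0.24, 1 past the test). Contractile (-0.27), elastic fibre (-0.24), collagen (-0.31, 1 higher and 1 lower past the test), TGF-beta targets (-0.40, with Tgfbi at 2.92 ± 0.47 the 1 past the test), dissociation (-0.14) and erythroid genes (-1.37) fell (adjusted p = 9.51e-07 to 0.0223, and 0.639 with an estimated correlation). Cluster 21, led by Pln and Nrip2, held 6.54% of smooth muscle cells in AAD, 10.5% in IMH-I, 21.5% in IMH-II and 13.8% in IMH-III. DESeq2 called 10 genes and 51 of the 73 were non-overlapping (32.8% of tested genes, 33.3% by chance).

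In endothelial cells 1 gene rose and 15 fell for aneurysm, all against IMH-I with its 50 cells. Lrg1, a modifier of TGF-beta signalling in vessels, fell by 2.90 (± 0.30, 767 CPM in AAD, 799 in IMH-I, 116 in IMH-II and 98.9 in IMH-III, adjusted p = 0.0307). Contractile genes fell with a median of -1.85 (adjusted p = 4.60e-17, and 0.544 with an estimated correlation), 2 of 16 past the test, Cnn1 and Myl9, and 11 adjusted over the list alone. Myl9 was 99.2 CPM in AAD, 547 in IMH-I, 56.8 in IMH-II and 77.3 in IMH-III. Collagen rose with a median of 1.10 (adjusted p = 1.78e-07, and 0.544 with an estimated correlation), 1 lower past the test, Postn, and 8 higher adjusted over the list alone. Modulated smooth muscle (0.61), angiogenic endothelium (0.77), heme handling (0.63), glycolysis (0.42) and dissociation genes (0.50) rose. Endothelial activation (-0.70), angiotensin receptor signalling (-0.45), interferon response (-0.33), MHC class II (-1.04) and cell cycle (-0.79) fell (adjusted p = 8.56e-09 to 0.0353, and 0.544 to 0.754 with an estimated correlation). Spp1 stood at 6.38 ± 0.81 (adjusted p = 0.0544) and Pgf, placental growth factor, at 3.43 ± 0.75 (adjusted p = 0.245). No gene passed with doublet calls kept, with the looser cell filter, with equal cell numbers or with libraries of at least 5 cells.

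In T cells no gene passed edgeR for aneurysm (482 with an unadjusted p under 0.05, 15 with DESeq2). Of unchanged genes in the simulation, which held 12018 genes, 4.69% reached that p, so a count of 482 can arise with no gene changed. In B cells 1 gene fell. It was Cfd, the complement factor D gene, at -6.09 ± 0.52 (adjusted p = 0.0168), named after its value was seen. Cfd also led the adipocyte-like cluster, which held 34 cells in AAD, 35 in IMH-I, 0 in AAA, 40 in IMH-II and 1 in IMH-III. Rgs1 in T cells was 247 and 394 CPM in AAD and IMH-I and 432, 982 and 756 CPM with aneurysm (1.00 ± 0.25, adjusted p = 1.00). Interferon response rose in B cells with a median of 0.65 and 14 of 15 positive (adjusted p = 9.29e-08, and 0.523 with an estimated correlation), and in T cells with 0.40 (adjusted p = 0.0423, and 0.919 with an estimated correlation). Erythroid genes fell with medians of -4.59 in T cells and -3.41 in B cells (adjusted p = 8.30e-09 and 4.87e-08, and 0.779 and 0.575 with an estimated correlation). Elastic fibre (median 0.28), collagen (0.11), matrix proteases (0.44), modulated smooth muscle (0.98), angiogenic endothelium (1.01), lipid-associated (0.78) and inflammatory macrophage (0.76) and dissociation genes (0.34) rose in B cells and contractile genes (-1.81) fell (adjusted p = 1.13e-08 to 0.0260, and 0.575 to 0.681 with an estimated correlation). In T cells modulated smooth muscle (0.54) and dissociation genes (0.33) rose and contractile genes (-2.51) fell (adjusted p = 1.38e-11 to 0.0448, and 0.538 to 0.779 with an estimated correlation). Of the B cells of AAA 54.6% lay in cluster 22, which held at most 2.50% of those of any other library. T cell counts were 94 without AAD, 96 without AAA, 100 without IMH-I and 27 without IMH-II. B cell counts were 41, 41, 71 and 3 in the same order and 4 without IMH-III.

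**Figure D3:**
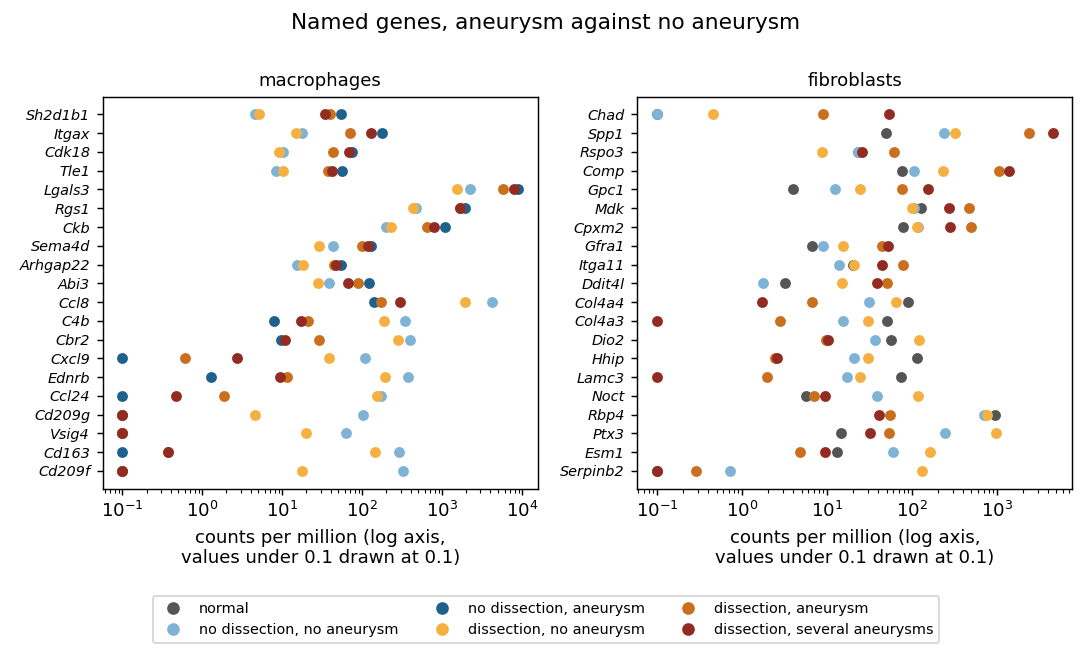
Points give CPM (log axis, values under 0.1 drawn at 0.1) of the named genes past the aneurysm test in macrophages and fibroblasts, 1 point per unsorted library. For Cd163 in macrophages AAD and IMH-I stand at 287 and 143, and AAA, IMH-II and IMH-III at or below 0.372.

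The sorted immune libraries, 1 per lesion and without a test, ask whether macrophages of the lesions with dissection differ from those of AAA when immune cells are taken alone. Single genes here were named only if the sorted and unsorted ratios had the same sign, so their agreement follows from the choice. Over all genes compared, the signs were alike for 56.3% in IMH-II and 51.3% in IMH-III. In IMH-II over AAA, Hmox1 was higher by 2.06 on the log2 scale in sorted cells (1048 CPM, counting interval 1028 to 1067, against 250 CPM) and by 3.57 in unsorted cells. Slc40a1, the iron exporter ferroportin, was higher by 3.46 and 2.90, Slc48a1, a heme transporter, by 1.48 and 1.24, and Gdf15, a stress cytokine, by 2.87 and 1.65. The growth factor Areg was lower, at -2.50 and -1.80. Of the heme and iron genes 9 of 10 were positive in both pairs for IMH-II (medians 0.72 sorted and 0.39 unsorted). For IMH-III 5 were positive sorted and 9 unsorted (-0.05 and 0.42). Interferon genes had medians of -0.77 and -0.69 in IMH-II, 0 of 8 positive in both pairs, and -0.36 and -0.82 in IMH-III, where Il18bp, Bst2 and Rtp4 were lower in both. Other lists had opposite signs sorted and unsorted in IMH-II, among them lipid-associated (1.02 and -0.19), resident-type (-0.80 and 1.43) and inflammatory macrophage genes (-0.64 and 0.14), matrix proteases (1.06 and -0.30), collagen (-0.35 and 1.73) and cell cycle (-1.01 and 0.20). Cluster 34, led by Folr2, Cd163 and Lyve1, held 8.62% of macrophages in sorted AAA and 2.61% in sorted IMH-II, against 0% and 4.64% unsorted. In IMH-III it held 8.50% sorted and 0.342% unsorted. At resolution 0.5 the list signs were alike for resident-type (1.39 and 1.79) and lipid-associated genes (1.27 and 0.07). They stayed opposite for inflammatory (-0.18 and 0.40), matrix protease (0.79 and -0.13) and collagen genes (-0.41 and 3.04). At resolution 2 resident-type (-0.56 and 1.45) and lipid-associated genes (0.92 and -0.17) were opposite as well. MHC class II had 0 of 6 positive in both pairs for IMH-II, and 6 sorted and 0 unsorted for IMH-III. Higher in both pairs for IMH-III were Ccl8 (1.49 and 1.08), Mrc1 (0.73 and 0.90) and Il10 (0.74 and 1.89). Across genes, which are not independent replicates, Pearson's r between sorted and unsorted ratios was 0.218 over 2871 genes for IMH-II and 0.277 over 2870 for IMH-III (Spearman's rho 0.153 and 0.113). At resolution 0.5 it was 0.591 and 0.446. The reference was the AAA lesion in both ratios, its sorted library for sorted cells and its unsorted library for unsorted cells. Its 174 sorted and 111 unsorted named macrophages are the fewest among the libraries compared here. Unnamed clusters 10, 16 and 26, whose leading class was macrophage, held 935, 597 and 138 sorted and 128, 34 and 14 unsorted AAA cells. Clusters 16 and 26 were mixed with T cell and B cell markers. At resolution 0.5 the named macrophage clusters held 628 and 729 sorted AAA cells. The cluster with 729 had a median doublet score of 0.107, against 0.0382 in the other and 0.111 and 0.0939 in mixed clusters 16 and 26. Whether the higher correlations at that resolution rest on such cells was not tested. The labels do not say whether sorted and unsorted cells came from the same mice.

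**Figure D4:**
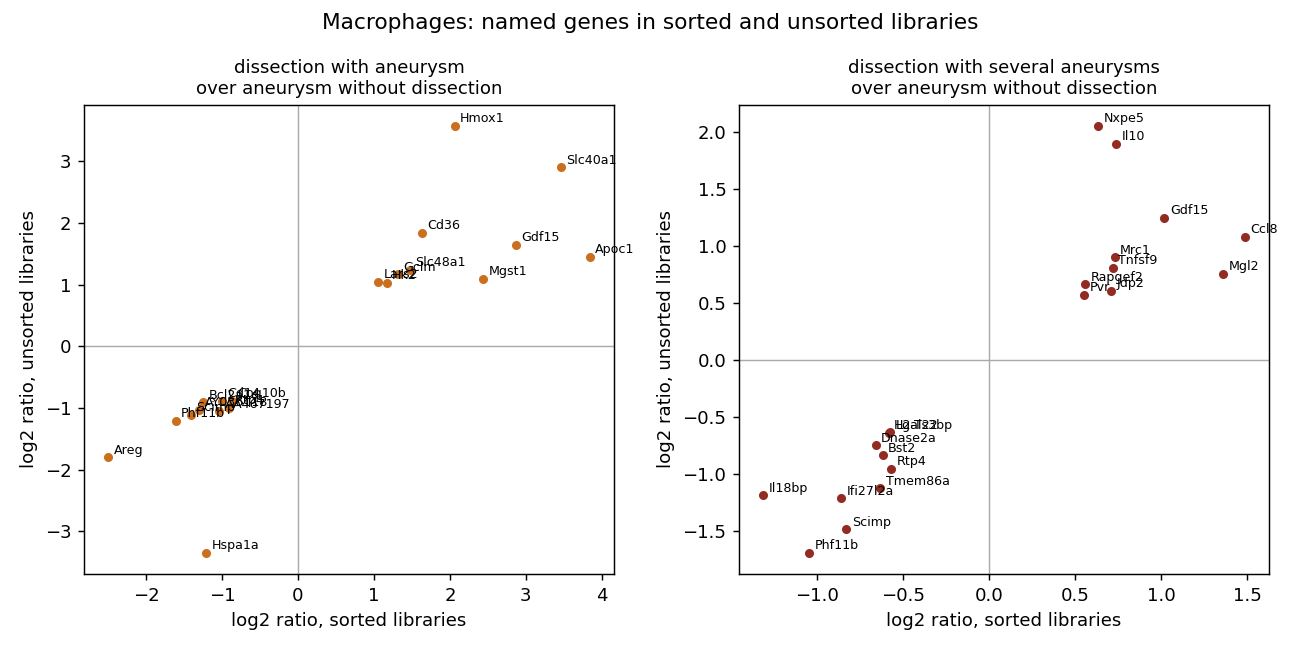
Points give, for each named gene, the log2 ratio of CPM over AAA in macrophages of the sorted library (horizontal axis) and of the unsorted library (vertical axis), for IMH-II and IMH-III. The genes were chosen for the same sign in both, so that agreement follows from the choice. Hmox1 of IMH-II lies at 2.06 and 3.57, and Areg at -2.50 and -1.80.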

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

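The predictions were written once the patterns were known, and 2 of the 8 tests, doublets in the IMH-III clusters and lower yield in AAA, were chosen only after the result was seen. After the tests had run, the 2 explanations by free RNA were put under a common pattern, with their tests and thresholds unchanged.

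Protease inhibitors, the genes that restrain matrix-degrading enzymes, had medians of opposite sign between cell classes under Ang II. In smooth muscle cells their median log2 ratio to the normal library was 0.40 over the 4 Ang II libraries (0.27 to 0.41), in fibroblasts it was -0.36 (-0.50 to -0.08) and in endothelial cells -0.81 (-1.35 to -0.45). Every library of one class lay on the other side of 0 from every library of the other, which is what put these values here. The difference between classes was not tested, and all ratios share the 1 normal library. The list itself passed in smooth muscle cells (adjusted p 0.00439, 0.279 with an estimated correlation) and not in fibroblasts (0.491) or endothelial cells (0.477).

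The first pattern weighed was that genes of other cell types moved with the groups in smooth muscle cells and lymphocytes. If free RNA from immune cells were the cause, MHC class II and inflammatory genes in smooth muscle cells should stand to their level in all cells as B, T and neutrophil markers do. Their ratio to those markers was 1.01 (0.518 to 1.07 over 4 Ang II libraries, all within the limit set), which is consistent with free RNA. If doublets with immune cells were the cause, the MHC class II median should fall by more than 1 without the highest doublet scores. It fell by 0.258 (4.45 to 4.19), within the limit set against doublets. Doublets with low scores stay in under that setting, so the test cannot exclude them. For collagen in lymphocytes the median ratio of T to B cell levels was 0.799 (0.645 to 0.974 over 5 libraries, all within the limit set), as free RNA from matrix cells would give. Expression of these genes by smooth muscle cells themselves was not ruled out, since a share below the free RNA cannot be seen.

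The second pattern was that 3626, 1843 and 1187 of the 12468 IMH-III cells lay in unnamed clusters 4, 15 and 19, led by matrix and cartilage genes, and as IMH-III is 1 pool of mice, whether they go with several aneurysms or with that pool was not tested. The highest median doublet score of the 3 clusters was 0.0382, between the 0.0595 and 0.0222 of smooth muscle clusters 1 and 21. With the 1634 highest scores of IMH-III left out, 3063, 1888 and 1111 of its 11244 cells still lay in clusters led by Eln, Col10a1 and Col2a1, which argues against doublets as the whole cause. Skeletal cartilage was taken to leave contractile genes within 2 times their level in lymphocytes (7.87 CPM). They stood at 38.5, 14.98 and 3.32 times, and cluster 19 did not pass the 4 times set against cartilage, so the test could not tell. Fibroblasts of that library, at 42.7 CPM, also lay above that limit, so cells other than muscle can pass it. The ratios of clusters 4 and 15 therefore do not count against cartilage. Cells of the smooth muscle lineage would hold contractile genes above fibroblasts (42.7 CPM), and the ratios were 7.09, 2.76 and 0.612, so cluster 19 again left it open.

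The last pattern was that 5914 of the 6100 cells of the unsorted AAA library lay in immune clusters. Loss of wall cells alone would leave the make-up of the immune cells as in the sorted AAA library, if both came from the same mice. Naive-like T and B cells were 43.5% of immune cells against 25.5%, a ratio of 1.70, outside the limit set for that account. The labels do not say whether the mice were the same, so the ratio cannot exclude it. The share was 56.8% in NA, 61.4% in AAD, 55.7% in IMH-I, 30.3% in IMH-II and 21.2% in IMH-III. Unsorted AAA thus lay within the range of the other unsorted libraries. A lymph node in the library was tested by 5 genes of node stroma and follicles summed over non-immune cells, 3077 CPM in AAA and 849 CPM in the next library, AAD, a ratio of 3.62 between the limits set, so this could not be told. The sorted IMH-III library reached 4457 CPM in 37 non-immune cells, and no biological explanation was tested.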

How the results depend on the processing

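The alternatives marked as added were chosen only after the results had been seen. No paired analysis was possible because the sorted and unsorted libraries of a lesion are not said to come from the same mice, and no other samples are matched. The alternative with sorted libraries added had sorting as a term and no block for lesion. Of named genes 142 results passed the test, and of their 1957 values under other settings 1438 kept the call, 512 lost it and 7 reversed in sign. Over all 428 results and 6232 values, 529 gained a call and 26 moved. Of the 142, 138 kept their call with upper quartile scaling, 139 without a filter, 117 with DESeq2, 99 with the looser cell filter, 63 with libraries of at least 5 cells and 58 with equal cell numbers. As a share of the results run, fewest calls held for libraries without dissection alone (8 kept, 56 lost and 2 reversed), without AAA (5 kept, 17 lost) and with cluster 10 added (4 kept, 18 lost). Unless a sentence says otherwise, the cause was not tested. The test found only part of the simulated changes, and libraries held as few as 50 endothelial cells and 99 fibroblasts. Whether depth sets that limit was not tested. Simulated 4-fold changes under Ang II were recovered in 21.9% of cases in T cells, 27.0% in B cells, 32.3% in endothelial cells, 45.5% in fibroblasts and 84.4% in smooth muscle cells.

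Counts below are in the order Ang II, dissection, aneurysm, and the main counts were 140, 7 and 73 in smooth muscle cells, 32, 3 and 341 in fibroblasts, and 79, 1 and 16 in endothelial cells. They were 0 for dissection and 96 for aneurysm in macrophages, 0, 0 and 1 in B cells and 0 in T cells. DESeq2 gave 402, 17 and 10 in smooth muscle cells, 351, 31 and 132 in fibroblasts, 569, 127 and 31 in endothelial cells, 9 and 599 in macrophages, 6 for dissection and 6 for aneurysm in B cells, and 4, 61 and 15 in T cells. No filter on low counts gave 540 and 19 for Ang II and dissection in smooth muscle cells, 635, 54 and 925 in fibroblasts, 439, 104 and 353 in endothelial cells, 9 and 1374 in macrophages, 58, 143 and 72 in B cells, and 92, 383 and 84 in T cells. Upper quartile scaling gave 70 for Ang II and 6 for dissection in fibroblasts, and 160.0 for aneurysm in macrophages.

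Doublet calls kept gave 33, 1 and 44 in smooth muscle cells, 79 for Ang II and 891 for aneurysm in fibroblasts, 0 for dissection and 0 for aneurysm in endothelial cells, 32 for aneurysm in macrophages and 1 in T cells. Doublets by expected rate, added, gave 42, 0 and 10 in smooth muscle cells, 62 for Ang II and 956 for aneurysm in fibroblasts, 343 for aneurysm in macrophages, 2 in B cells and 4 in T cells. In endothelial cells that setting gave 33 for Ang II and 93 for dissection, but IMH-I fell below 50 cells and was left out as well, so 2 choices changed. The looser cell filter gave 22 for aneurysm in smooth muscle cells, 62 for Ang II and 1019 for aneurysm in fibroblasts, 0 for dissection and 0 for aneurysm in endothelial cells and 3 for aneurysm in macrophages. Equal cell numbers, which leave fewer counts, gave 10, 1 and 37 in smooth muscle cells, 0, 0 and 157 in fibroblasts, 24 for Ang II and 0 for aneurysm in endothelial cells, 202 for aneurysm in macrophages, 0 in B cells, and 20 for dissection in T cells. Libraries of at least 5 cells, added, gave 281 for Ang II and 42 for aneurysm in smooth muscle cells, 1, 0 and 58 in fibroblasts, 0, 0 and 0 in endothelial cells. It allowed Ang II in macrophages to be tested, with 0 genes past the threshold and 1456 by unadjusted p.

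Resolution 0.5 gave 5 for dissection and 512 for aneurysm in fibroblasts, 9 for aneurysm in endothelial cells, 1 for dissection and 33 for aneurysm in macrophages, and correlations of 0.591 and 0.446 between sorted and unsorted ratios in IMH-II and IMH-III. Resolution 2 gave 59 for Ang II and 837 for aneurysm in fibroblasts, 176 for aneurysm in macrophages, 1 in T cells, and correlations of 0.256 and 0.178. In endothelial cells it gave 262 for Ang II and 37 for dissection, again with IMH-I left out, and leaving out IMH-I alone gave 491 and 160.0. Libraries without dissection alone against normal, which in wall cells is AAD against NA, 1 library each, gave 74 in smooth muscle cells, 1 in fibroblasts and 0 in endothelial cells. Aneurysm as a term gave 51, 54, 2 and 1 for dissection in smooth muscle cells, fibroblasts, endothelial cells and T cells. Sorted libraries added gave 348 and cluster 10 added, an added alternative, 8 for aneurysm in macrophages. With an estimated correlation 0 lists passed in all 17 class comparisons, and with no filter 6 lists passed for aneurysm in macrophages, 9 for Ang II and 6 for aneurysm in B cells, against 3, 3 and 11.

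Leaving out 1 library at a time gave 133 to 718 genes for Ang II and 27 to 76 for dissection in smooth muscle cells, 61 to 867 and 10 to 338 in fibroblasts, and 0 to 491 and 0 to 160 in endothelial cells. For aneurysm fibroblasts gave 202. Macrophages gave 0 to 16 for dissection and 3 to 237 for aneurysm, B cells 0 to 3, 0 to 31 and 3 to 71, and T cells 0 to 6, 0 to 183 and 0 to 100. The T cell difference in share ran from -41.7 to -13.8 points and that of plasma cells from -3.01 to -1.31. As a share of non-immune cells the endothelial difference was -7.57 points (-7.70 at the lower Ptprc level, added), against 0.484 of all cells, that of Schwann cells 0.911 (0.922), against 0.321, and as a share of immune cells the macrophage difference was 17.39 points (17.36), against 6.78.

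Cpxm2 in fibroblasts for aneurysm reversed to -0.17 with libraries of at least 5 cells. In endothelial cells under Ang II, Hbb-bt reversed to 5.20 and Hba-a2 to 5.33 with equal cell numbers, to 1.03 and 0.80 with libraries without dissection alone, and to 9.03 and 9.75 with doublets by expected rate, where IMH-I was left out too. Not run were Ang II in macrophages with sorted libraries added, since the normal library had 18 macrophages, aneurysm in wall cells without any 1 of the libraries with dissection, and removal of the lone normal library.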

Other observations

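None of the values in this part were tested, and the genes and clusters were chosen after the results were seen. The matrix-rich cells of IMH-III differed among themselves. Cluster 4, 29.1% of its cells, held Eln, the core protein of elastic fibres, at 17055 CPM, against 4742 CPM in the named smooth muscle cluster 1 of that library, and Mgp, an inhibitor of calcification, at 68180.5 CPM against 14835 CPM. It also held Acta2, smooth muscle actin, at 6227 CPM and Myh11 at 482 CPM, against 26667 and 3067 CPM in cluster 1 and 739 and 36.0 CPM in fibroblast cluster 18. Cluster 15, 14.8% of cells, held Col10a1, the collagen of hypertrophic cartilage, at 1883.5 CPM and Myh11 at 72.1 CPM. Cluster 19, 9.52% of cells, held the cartilage collagen Col2a1 at 2205 CPM, Cytl1 at 2467 CPM, the cartilage regulator Sox9 at 278 CPM and the bone matrix gene Ibsp at 46.6 CPM, while Myh11 was 23.0 CPM. Spp1 was 6926 CPM in cluster 4, 4987 CPM in cluster 15 and 7614 CPM in cluster 19. Cluster 4 was not particular to IMH-III among wall cells, since it held 98 of the 186 non-immune cells of AAA beside 3626 of 7549 in IMH-III. It held 119 of 1990 non-immune cells in IMH-II, 42 of 1314 in AAD, 12 of 1783 in IMH-I and 10 of 6938 in the normal library.

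Interleukin-17-type T cells lay in clusters 14 and 29. Cluster 14, led by Il17a and Trdc, held 9.46% of T cells in the normal library and 17.5% in IMH-II, against 2.83% in AAD, 0.881% in AAA, 0.998% in IMH-I and 5.50% in IMH-III. Cluster 29, led by Il22, Il17f and Il17a, held 0.676% of T cells in the normal library, 4.21% in IMH-II, 0.830% in AAD, 1.15% in AAA, 0.630% in IMH-I and 1.03% in IMH-III. Of all immune cells cluster 14 made up 6.59%, 3.52% and 11.0% in the sorted AAA, IMH-II and IMH-III libraries and 0.507%, 3.54% and 0.976% in the unsorted ones, and cluster 29 made up 2.21%, 0.592% and 1.14% and 0.659%, 0.850% and 0.183%. Regulatory-type T cells, cluster 9 with Foxp3 and Ctla4, were 9.46% of normal T cells and 17.2% to 25.8% in the Ang II libraries. A neutrophil-like cluster led by Siglecf and Il23a made up 2.01% of IMH-I (95% exact interval 1.72% to 2.32%) and 3.12% of IMH-II, 0.192% of IMH-III, 0.150% of AAD, and 0 of 6100 cells of AAA, with an upper limit of 0.0605%. It was 0.870%, 5.59% and 1.88% of the sorted AAA, IMH-II and IMH-III libraries. Cluster 10, led by Acp5, Arg1, Cxcl3 and Pf4, held all 8 macrophage markers. It was left unnamed because more platelet or megakaryocyte markers stood among its top genes. It made up 0.0133% of the normal library, 0.629% of AAD, 2.10% of AAA, 1.28% of IMH-I, 6.44% of IMH-II and 1.17% of IMH-III. In the sorted libraries it was 7.20% of AAA, 8.68% of IMH-II and 6.39% of IMH-III.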
